A study of Mus musculus with 13 samples.

How the data were processed

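DNA barcodes were sequenced from sorted leukaemia cells of 6 mice, 3 Ptprca and 3 NSG, with 1 bone marrow and 1 spleen library per mouse, and from 1 baseline sample of haematopoietic progenitors. Groups and mouse numbers were taken from the sample titles. Per the labels' protocols, progenitors were transduced with the barcode library, cell lysates were split into technical replicates, and barcodes were amplified in 2 rounds of PCR with well-specific indices. Bowtie 1.2.2 and R 3.6 were used, per the submitters' processing notes. Their settings are not given in the sources used here.

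The authors deposited 1 table of CPM values, with a line per barcode and a column per library, and each column summed to 1000000. All 2795 values under 60 CPM were sums of whole multiples of 2 steps (tolerance 1e-06 CPM), as the mean CPM of 2 repeats gives, while 10.2% to 38.6% per library were whole multiples of 1 step. The steps gave the reads of each repeat, and 5091 of 5093 values above 0 and under 1000 CPM were resolved into the reads of both repeats. The floor of a library was set at 3 reads in the shallower repeat. The 95% Wilson intervals of baseline shares used each share and the summed reads, and are approximate for a mean of repeats. Total reads per library ran from 2484519 to 5252942, and the floor from 0.575 to 8.80 CPM. Because single reads were averaged over repeats of different depth, no count model was fitted.

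Barcodes at 10 CPM or more in at least 3 of the 12 disease libraries (373 barcodes) were tested with limma 3.58.1 in R 4.3.3 on log2(CPM + 1), with a variance trend and Benjamini-Hochberg adjustment at 0.05. The strain comparisons used the 6 libraries of an organ. The organ contrast, over both strains and within each, and the interaction used 4 group means over 12 libraries. Of the tested barcodes, 1 was at 0 in all spleens, and its zero variance was offset by limma. The procedure was tested on simulated data with the observed means and spreads of the 373 barcodes and 60 changed barcodes. In bone marrow it recovered 0, 5 and 6 of 20 barcodes changed by 2, 4 and 6 on the log2 scale, and in spleen 0, 0 and 6 of 20, with 0 false calls in each.

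The effective number of barcodes, similarity, dominance and baseline relation were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. Differences in per-library measures were tested by exact permutation, two-sided, over a family of 35 tests (7 measures in 5 comparisons). The similarity tests, one-sided, form a family of 4. Dominance was set at 1% of a library. Libraries with the same mouse number in their titles come from the same animal, and the deviations of bone marrow and spleen from their group means correlated at 0.773 to 0.796 in Ptprca and 0.208 to 0.254 in NSG mice over the 373 barcodes.

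Before the data were examined, tests, alternatives, barcode classes and a rule for named barcodes were fixed. The rule took the 10 barcodes with the highest mean CPM at disease, up to 5 called barcodes per direction and comparison whose groups did not overlap, the 5 most abundant at baseline, and every barcode at 1% or more in all 6 mice. It gave 20 barcodes. The alternatives were other pseudocounts (10 and 0.1), filters, scaling, variance priors, diversity and similarity measures, dominance limits, the mouse as a block or random effect, and each mouse left out. The measures other than the effective number and the inverse Simpson index, the test of their interaction, the organ contrast within each strain, the leaving out of the most abundant barcode, of 2 bone marrow libraries and of barcodes under a mean of 1000 CPM, the within-strain matchings and the restriction to barcodes seen at disease were added after seeing the data.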

Results

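Heritable DNA barcodes were counted in leukaemia cells driven by MLL-AF9, a fusion oncogene of acute myeloid leukaemia, to follow which founder cells grew out in hosts with and without adaptive immunity. The SPLINTR library places a short genomic tag in each transduced haematopoietic progenitor, and all descendants of that cell carry it. The hosts were 3 Ptprca mice, an immunocompetent strain congenic with C57BL/6, and 3 NSG mice, which lack T, B and natural killer cells. Each mouse gave 1 bone marrow and 1 spleen library at disease, and 1 baseline library sampled the transduced progenitors. The table held 2505 barcodes in 13 libraries as CPM, reads scaled to 1000000 per library. Each value was the mean of 2 technical repeats, which together held 2484519 to 5252942 reads per library.

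The technical repeats set the precision of low values. For barcodes between 100 and 1000 CPM, the SD of the log2 ratio between repeats was 2.26, 1.57 and 1.71 in the spleens of NSG mice 4, 5 and 6, and 0.585 or less in each of the other 10 libraries. Of the barcodes between 10 and 1000 CPM, 72.3%, 59.8% and 73.8% were seen in both repeats of those 3 spleens, against 89.5% or more elsewhere. A floor of 3 reads in the shallower repeat corresponded to between 0.575 and 8.80 CPM, the highest value belonging to Ptprca mouse 3 bone marrow, in which 1 repeat held 170453 reads. Intervals and floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

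The first comparison asked which barcodes differed in bone marrow between the immunodeficient and the immunocompetent host. A single barcode, GFP_Barcode_52804, made up 20.0% ± 3.01 (SD, n = 3) of NSG bone marrow and 0.266% ± 0.00355 (SD, n = 3) of Ptprca bone marrow, a 75.3-fold ratio of means. At baseline it held 0.0560% of the library (95% Wilson interval 0.0540% to 0.0582%). In contrast, 3 barcodes were lower in NSG mice. GFP_Barcode_44375 held 3.79% ± 0.534 of Ptprca and 0.0458% ± 0.0269 of NSG bone marrow, GFP_Barcode_24738 held 2.39% ± 0.906 and 0.128% ± 0.0204, and GFP_Barcode_122306 held 1.19% ± 0.118 and 0.0116% ± 0.00668 (SD, n = 3 each).

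Of 373 barcodes tested in bone marrow with limma, 4 passed a Benjamini-Hochberg adjusted p of 0.05, 1 higher and 3 lower in NSG mice. An unadjusted p under 0.05 was found for 59. The balance of directions depended on the processing. Calls were mostly higher with a filter of 100 CPM (8 higher, 6 lower), without a variance trend (8 higher, 4 lower) and without a filter (6 higher, 4 lower). They were mostly lower with centred log-ratios (1 higher, 5 lower) and with either other pseudocount (1 higher, 3 lower each). On the log2(CPM + 1) scale, which understates changes of low barcodes, GFP_Barcode_52804 differed by 6.22 (SE 0.39, limma adjusted p = 0.000166) and GFP_Barcode_44375 by -6.58 (SE 0.82, limma adjusted p = 0.0110). The differences of GFP_Barcode_24738 and GFP_Barcode_122306 were -4.17 and -6.82, each with a limma adjusted p of 0.0283. With the mouse as a random effect over the 12 libraries, 3 barcodes were called, 2 higher and 1 lower in NSG mice. GFP_Barcode_24738 and GFP_Barcode_122306 then did not pass (limma adjusted p = 0.0712 each), and GFP_Barcode_28531 did, at a log2 difference of 10.70 (limma adjusted p = 0.0275). In the fit of bone marrow alone, the count was 1 or 2 when any single mouse was left out, and GFP_Barcode_52804 was called in each of these 6 fits. It was 0 without the bone marrow libraries of mouse 1 and mouse 5, left out after the data were seen because they shared rare barcodes, and GFP_Barcode_52804 then differed by 6.26 (limma adjusted p = 0.136).

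The effective number of barcodes also separated the strains in bone marrow. This number, the exponential of the Shannon entropy of the shares, was 66.0 ± 2.65 in Ptprca and 42.2 ± 1.35 in NSG bone marrow (SD, n = 3 each). Barcodes at 1% or more numbered 30 ± 2.65 and 17.7 ± 1.15, while barcodes at 10 CPM or more numbered 242 ± 12.5 and 315 ± 21.9. Each of these 3 measures separated all mice of the strains, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 mice allow (adjusted p = 0.14 over 35 exact tests). With GFP_Barcode_52804 left out, an alternative chosen after seeing the data, the difference in effective number went from -23.7 to -7.17 (exact permutation p = 0.3).

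**Figure D1:**
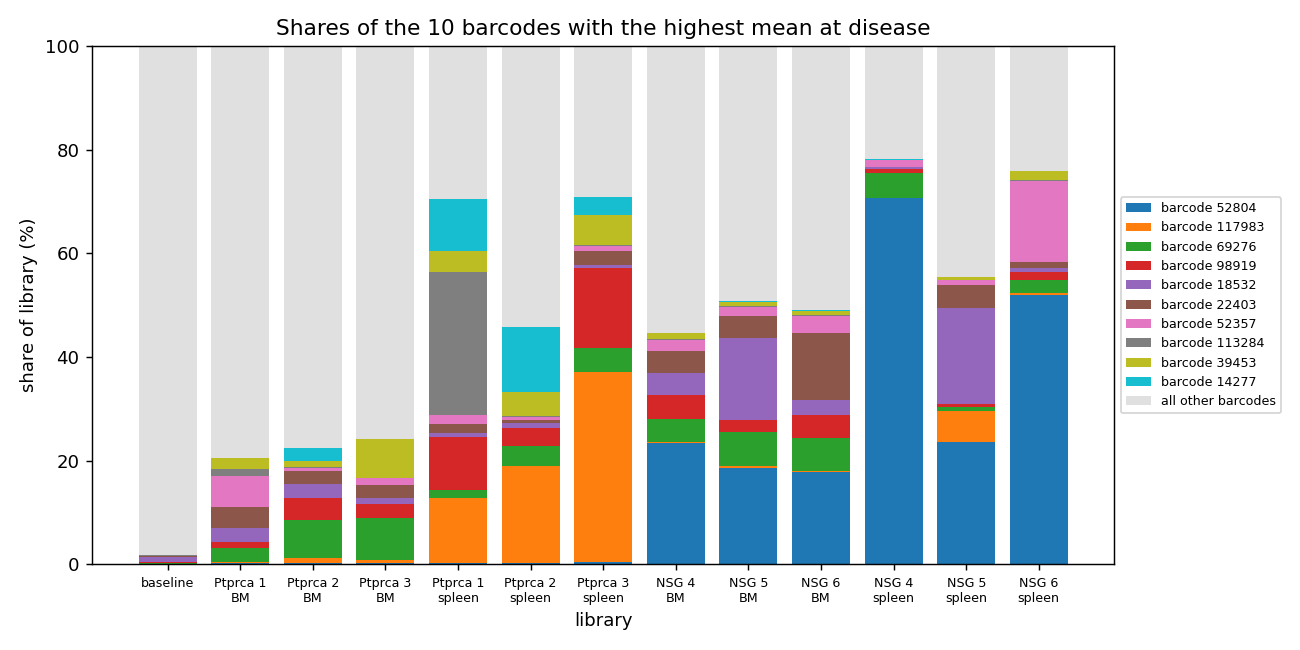
Stacked bars give the share of each library, in percent, held by the 10 barcodes with the highest mean over the 12 disease libraries, with all other barcodes in grey; libraries are on the horizontal axis. GFP_Barcode_52804 spans 17.9% to 70.7% of the NSG libraries and at most 0.361% of any Ptprca library.

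The same question was asked of spleen. GFP_Barcode_52804 made up 23.7%, 52.0% and 70.7% of the NSG spleens and 0.287% ± 0.0919 (SD, n = 3) of Ptprca spleens, a 170-fold ratio of means. GFP_Barcode_28531 held 0.481% ± 0.443 of NSG spleens and was at 0 in all 3 Ptprca spleens. Against the mean floor of the Ptprca spleens, 0.595 CPM, it was at least 8085-fold higher in NSG mice. The NSG spleens of mice 4, 5 and 6 held 0.0368%, 0.923% and 0.484%. This bound rests on their mean and would be lower without mouse 5. The fitted log2 difference of GFP_Barcode_28531 is no bound. At baseline this barcode held 1.03% of the library, more than in any of the 3 NSG spleens. The fold therefore does not show a rise above the starting share in NSG spleens. In bone marrow, NSG mouse 6 was above that share, at 1.42%, and NSG mice 4 and 5 were below it, at 0.0239% and 0.611%. With a single baseline library, no test against baseline was made. GFP_Barcode_14277 held 8.68% ± 4.70 of Ptprca and 0.0189% ± 0.0164 of NSG spleens, and GFP_Barcode_9344 held 1.68% ± 2.00 and 0.00266% ± 0.00460 (SD, n = 3 each). The most abundant barcode of Ptprca spleens, GFP_Barcode_117983, held 22.6% ± 12.6 there and 2.05% ± 3.33 in NSG spleens, a difference that did not pass (limma adjusted p = 0.376).

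In spleen, limma called 4 of 373 barcodes, 2 higher and 2 lower in NSG mice, with 37 at an unadjusted p under 0.05. The differences on the log2(CPM + 1) scale were 7.32 for GFP_Barcode_52804 (SE 0.91, limma adjusted p = 0.00220), -10.77 for GFP_Barcode_14277 (SE 2.07, limma adjusted p = 0.0423), -11.19 for GFP_Barcode_9344 (SE 2.20, limma adjusted p = 0.0423) and 11.31 for GFP_Barcode_28531 (SE 2.32, limma adjusted p = 0.0449). The effective number of barcodes was 18.8 ± 4.14 in Ptprca and 13.6 ± 10.7 in NSG spleens (SD, n = 3 each; exact two-sided permutation p = 0.5, adjusted p = 0.583). Without GFP_Barcode_52804 this difference turned from -5.25 to 13.9 (exact permutation p = 0.1), it ran from -11.3 to -1.08 with each mouse left out, and in those fits the count of called barcodes was 0 to 2 and GFP_Barcode_52804 was not called. The NSG shares come from the spleen libraries whose repeats differed most.

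**Figure D2:**
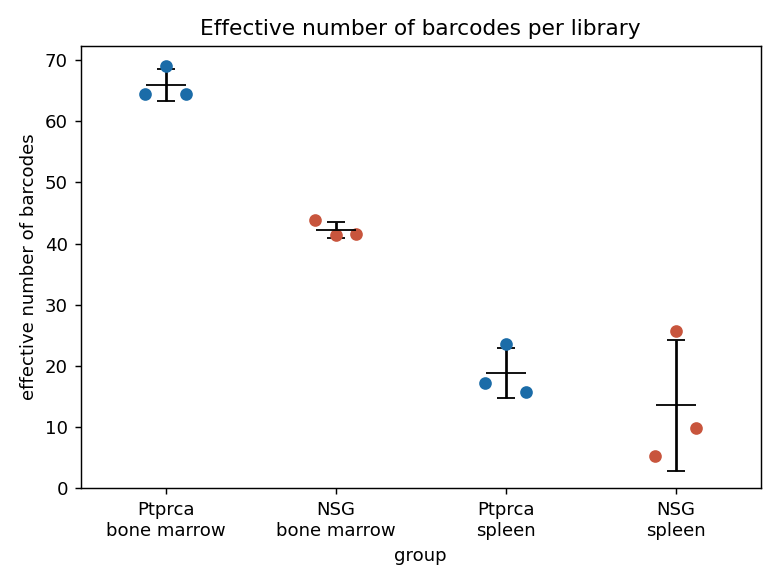
Points give the effective number of barcodes of each library, bars the mean and SD of 3 mice, by strain and organ. The Ptprca bone marrows lie between 64.4 and 69.0 and the NSG bone marrows between 41.4 and 43.8, while every spleen lies at 25.7 or below.

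Spleen was compared with bone marrow over both strains. Every mouse had fewer effective barcodes in spleen than in bone marrow, with a mean difference of -37.9 (SD 12.6 over 6 mice). The largest barcode held 24.7 percentage points more of the spleen than of the bone marrow library on average, and the number of barcodes at 1000 CPM or more fell by 39.8. GFP_Barcode_117983 held 0.549% ± 0.347 of Ptprca bone marrow and 22.6% ± 12.6 of Ptprca spleen, and GFP_Barcode_14277 held 0.930% ± 1.39 and 8.68% ± 4.70 (SD, n = 3 each). Neither passed the test over both strains (limma adjusted p = 0.720 and 0.830).

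The exact two-sided permutation test of 6 against 6 libraries gave p = 0.00216 for the effective number, the smallest it allows (adjusted p = 0.0152 over 35 exact tests). With the mouse as the block, the exact sign-flip test on the 6 pairs gave p = 0.0313, also the smallest possible, with an adjusted p of 0.0841. The effective number was lower in spleen in 6 of 6 mice. Per barcode, limma called 0 of 373 between the organs, with 34 at an unadjusted p under 0.05, and 0 with the mouse as a block, with 61 at an unadjusted p under 0.05. Within each strain, contrasts added after seeing the data, limma called 0 barcodes in Ptprca mice (8 at an unadjusted p under 0.05) and 1 in NSG mice (42 at an unadjusted p under 0.05). The latter was GFP_Barcode_9344, with a spleen minus bone marrow difference of -9.85 on the log2(CPM + 1) scale (SE 1.79, limma adjusted p = 0.0137) and at 0 in 2 of the 3 NSG spleens. With the mouse as a block, 0 were called in either strain. Both within-strain contrasts used 1 spread per barcode over both strains, including the NSG spleens, whose repeats differed most. The 0 calls in Ptprca mice therefore do not show that their organs were alike. There GFP_Barcode_117983 differed by 5.44 on the log2(CPM + 1) scale, with an SE of 2.38.

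Whether the organ difference itself differed between strains was tested as an interaction. GFP_Barcode_9344 had the lowest adjusted p among the named barcodes. It was at 1.08% ± 0.916 in bone marrow and 1.68% ± 2.00 in spleen of Ptprca mice, and at 0.480% ± 0.281 and 0.00266% ± 0.00460 in NSG mice (SD, n = 3 each). The limma interaction was -10.44 on the log2 scale (SE 2.52, adjusted p = 0.256). No barcode of 373 passed (0 calls, 15 at an unadjusted p under 0.05), and 0 passed with the mouse as a block (24 at an unadjusted p under 0.05). For the effective number, the spleen minus bone marrow difference was 18.5 less negative in NSG mice (exact permutation p = 0.1, the smallest possible, adjusted p = 0.14). This holds for differences only. As ratios of bone marrow to spleen the strains overlapped, at 3.75, 2.93 and 4.09 in Ptprca mice 1, 2 and 3. In NSG mice 4, 5 and 6 the ratios were 8.36, 1.61 and 4.24.

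The design also asked whether the same founder cells dominated in separate animals. Taking the mean of both organs, 50 barcodes reached 1% in at least 1 mouse, and GFP_Barcode_69276, GFP_Barcode_98919 and GFP_Barcode_22403 reached it in all 6. GFP_Barcode_69276 held 6.03% ± 2.88 of Ptprca and 5.71% ± 1.23 of NSG bone marrow, with limma adjusted p = 0.962 between strains. In 10000 reshuffles of barcode identity within each mouse and within 10 bins of baseline CPM, the highest number reaching 1% in every mouse was 0 (permutation p = 0.0001, the smallest the reshuffles give). In spleen taken alone, 0 barcodes reached 1% in all 6 mice.

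By class, 12 barcodes were dominant in at least 1 mouse of each strain, 27 only on the Ptprca side and 11 only on the NSG side. Among the 27, 2 were lower in NSG mice and 25 did not pass, in each organ, with 5 passing in each organ when adjusted over the list alone. Among the 11, 1 was higher in NSG mice and 10 did not pass, in each organ, with 1 in bone marrow and 2 in spleen when adjusted over the list alone. Of the 12 shared barcodes limma called 0 in either organ, also adjusted over the list alone, with 0 in bone marrow and 3 in spleen at an unadjusted p under 0.05. These classes were assigned from the same libraries, so their direction is not independent evidence. One-sided barcodes numbered 38 for the real strains and 26 to 31 for the 9 other ways to part the 6 mice.

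Similarity of composition was measured as 1 minus the Bray-Curtis distance of shares. Bone marrows of NSG mice resembled one another most, at 0.618 ± 0.0126, against 0.437 ± 0.0400 among Ptprca bone marrows (SD over 3 pairs each) and 0.362 between strains. Ptprca spleens had a similarity of 0.462 ± 0.0244 to one another, while each of these mice had 0.294, 0.380 and 0.375 between its own bone marrow and spleen. In NSG mice 4, 5 and 6 the similarity of the organs of 1 mouse was 0.420, 0.602 and 0.418.

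Within-strain similarity exceeded between-strain similarity by 0.166 in bone marrow and 0.309 in spleen (one-sided exact permutation p = 0.1 each, the smallest possible; adjusted p = 0.1 over 4 tests). With GFP_Barcode_52804 left out, an alternative chosen after seeing the data, these differences were 0.0882 and 0.150 (p = 0.1 each by exact permutation). Organs of the same mouse were more alike than organs of different mice by 0.142 (one-sided exact permutation p = 0.00139 over 720 matchings, adjusted p = 0.00556). Against other mice of the same strain only, a test added after seeing the data, the excess was 0.0514 (exact permutation p = 0.0278 over 36 matchings, adjusted p = 0.0556). The rank correlation across tested barcodes, which are not independent replicates, was 0.886 to 0.905 between the organs of each Ptprca mouse and 0.546 to 0.627 in NSG mice, whose spleens had the noisiest repeats.

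**Figure D3:**
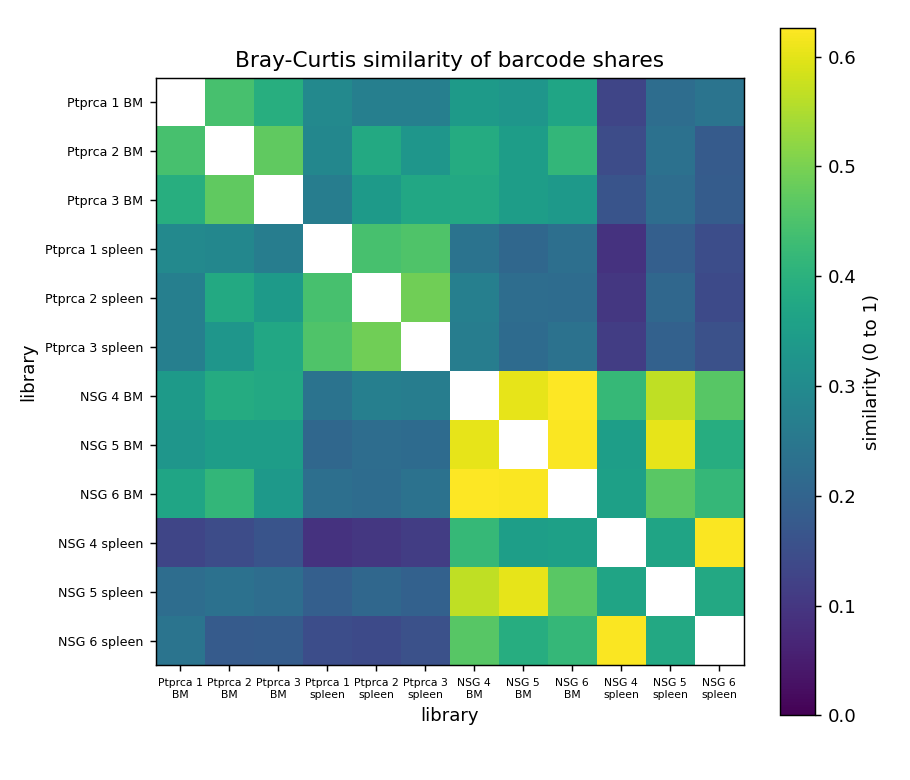
Colour gives the Bray-Curtis similarity of barcode shares, from 0 upward, for each pair of the 12 disease libraries named on both axes. NSG bone marrow pairs lie between 0.603 and 0.626, and spleen pairs of different strains between 0.0921 and 0.209.

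The last comparison set disease against the starting population. The baseline library had 346 effective barcodes. Disease libraries had 19.1% ± 0.764 of this number in Ptprca bone marrow, 12.2% ± 0.390 in NSG bone marrow, 5.44% ± 1.195 in Ptprca spleen and 3.92% ± 3.10 in NSG spleen (SD, n = 3 each). The 5 barcodes most abundant at baseline shrank, while GFP_Barcode_18532, at 1.01% at baseline, held a mean of 4.26% at disease. GFP_Barcode_129 held 4.94% at baseline (95% Wilson interval 4.92% to 4.95%) and a mean of 0.00946% at disease. NSG mouse 4 bone marrow, at 0.0869%, gave most of this mean, and 6 of the 12 disease libraries were at 0. GFP_Barcode_27492 held 5.29% (5.27% to 5.31%) at baseline and a mean of 0.165% at disease. GFP_Barcode_132107, which kept a near-constant ratio to GFP_Barcode_27492, held 4.68% (4.66% to 4.70%) and 0.160%. GFP_Barcode_22402 held 1.57% at baseline (1.56% to 1.59%) and was at 0 in 11 of the 12 disease libraries and at 0.544 CPM, below that library's floor of 0.816 CPM, in the spleen of NSG mouse 6. GFP_Barcode_117983 went the other way, from 0.00557% (0.00494% to 0.00625%) to a mean of 6.35%. The Ptprca spleens, at 12.4%, 18.7% and 36.7%, carried most of this mean. The highest library outside them was NSG mouse 5 spleen, at 5.89%. In NSG mouse 4 spleen the barcode was at 0.799 CPM, below its baseline value of 55.7 CPM. With 1 baseline library, these differences have no replicate check and no test was made.

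Starting abundance ordered the barcodes in part. Of 2394 barcodes present at baseline, 568 (23.7%) were seen at 10 CPM or more in at least 1 disease library. In 3 equal bins of rising baseline abundance this share was 5.39% (95% Wilson interval 4.02% to 7.18%), 19.8% (17.2% to 22.7%) and 46.0% (42.6% to 49.5%). Of 184 barcodes at 1000 CPM or more at baseline, 77 were not seen at 10 CPM in any disease library. Spearman's rho across barcodes between baseline and mean disease CPM was 0.460, and 0.255 among the 689 barcodes also above 0 at disease, an alternative added after seeing the data. Barcodes are not independent replicates, so no p is given.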

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

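Alternatives that left out the most abundant barcode, 2 bone marrow libraries or barcodes under a mean of 1000 CPM, or restricted the baseline relation to barcodes seen at disease, and the organ contrasts within a strain, were chosen after seeing the data. The planned count test was not run, because reads were averaged over repeats of unequal depth. The organ contrast and the interaction had 0 calls under every alternative run, and with the mouse as a block, and so did the organ contrast within Ptprca mice. Within NSG mice its 1 call was another barcode without a variance trend and became 0 without a filter, 0 with centred log-ratios, 0 with the mouse as a block, 0 without the bone marrow libraries of mouse 1 and mouse 5, and 0 to 6 with each mouse left out, 6 only without mouse 5. For the effective number in spleen against bone marrow, the block moved the exact permutation p from 0.00216 to 0.0313 and its adjusted p from 0.0152 to 0.0841. With the mouse as a random effect, 3 barcodes were called between strains in bone marrow, 2 of them among the 4, and 6 in spleen (2 higher and 4 lower in NSG mice), among them all 4. The strain count in bone marrow, 4 with 1 higher and 3 lower in NSG mice, was 10 without a filter (6 higher, 4 lower), 14 with a filter of 100 CPM (8 higher, 6 lower), 12 without a variance trend (8 higher, 4 lower), 1 (lower in NSG mice) without the most abundant barcode, 0 without the bone marrow libraries of mouse 1 and mouse 5, and 1 to 2 with each mouse left out. In spleen the 4 calls became 1 with a pseudocount of 0.1, 0 without a filter, 7 with a filter of 100 CPM and 7 with centred log-ratios (3 higher, 4 lower each), 0 without a variance trend, 0 without the most abundant barcode, 2 among barcodes at a mean of 1000 CPM or more, and 0 to 2 with each mouse left out, 2 only without mouse 5. The cause was not tested, except that leaving out mice or libraries reduces the samples. Simulated barcodes changed by 2 on the log2 scale were recovered in 0 of 20 cases, so low counts of calls do not show that barcodes were alike.

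The strain difference in effective number of barcodes in spleen was reversed without the most abundant barcode, at 13.9; by construction this shows what that barcode contributes. The ratio to baseline was 0.189 with the inverse Simpson index against 0.102, and rho with baseline was 0.389 for barcodes at 10 CPM or more at baseline, 0.255 among those seen at disease, and 0.417 to 0.468 with each mouse left out, lowest without mouse 6. Barcodes dominant in every mouse numbered 7 at 0.5%, 1 at 2% and 0 in spleen alone, against 3.

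Of 122 alternative values for the 8 called strain differences of named barcodes, 57 kept the call, 65 lost it and 0 changed sign. GFP_Barcode_52804 kept its bone marrow call in 14 of 15 alternatives, with limma adjusted p from 1.79e-05 to 0.136, and its spleen call in 6 of 14, from 1.30e-06 to 0.185. Differences that did not pass changed sign in 14 values. With centred log-ratios in bone marrow, GFP_Barcode_69276 gave -0.66, GFP_Barcode_98919 -0.053 and GFP_Barcode_52357 -0.30. Without mouse 1 and mouse 5 bone marrow, GFP_Barcode_69276 gave -0.55, and without the most abundant barcode it gave 0.53 and GFP_Barcode_22403 0.051 in spleen. With each mouse left out, bone marrow values ran from -0.45 to 0.33 for GFP_Barcode_69276, -0.29 to 1.30 for GFP_Barcode_52357 and -1.91 to 0.015 for GFP_Barcode_9344, and spleen values from -1.14 to 0.19 for GFP_Barcode_69276, -0.77 to 2.32 for GFP_Barcode_18532 and -2.34 to 0.63 for GFP_Barcode_22403.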

Other observations

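All tests in this part were chosen after the results were seen. The scan of 7260 pairs among 121 barcodes present at 10 CPM or more in at least 10 disease libraries found 4 pairs whose log2 ratio had an SD under 0.5 over 12 libraries, a limit set after seeing the values, against a median SD of 3.64 over all pairs. GFP_Barcode_132107 stood at 90.2% of GFP_Barcode_27492 at disease and 88.5% at baseline, although their baseline shares were 29.3 and 32.1 times their mean disease shares. GFP_Barcode_7083 stood at 12.8% and 11.1% of GFP_Barcode_69276, GFP_Barcode_117016 at 17.6% and 15.9% of GFP_Barcode_618, and GFP_Barcode_94075 at 59.7% and 50.8% of GFP_Barcode_7722; these pairs were named after their values were seen. A candidate explanation is that each pair sat in 1 founder cell. The baseline ratio, not used to pick the pairs, lay within 0.25 log2 of the disease ratio in 100% of the pairs and in 5.90% of the others, and 100 permutations of each barcode's libraries within groups gave at most 1 such pair. Reads miscopied from the partner would keep a constant ratio as well, at 12.8% to 90.2% of the partner in these pairs; barcode sequences were not used here, so this stays open. The numbers of barcodes given here may therefore exceed the number of founder cells.

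The host difference of GFP_Barcode_52804 was set against carry-over between libraries. A library carried over brings all its dominant barcodes at 1 rate. The rate needed to supply the whole share of GFP_Barcode_52804 ran from 0.253 to 3.95 over 24 ordered pairs of libraries from different NSG mice. The rate that the donor's other barcodes at 10000 CPM or more allowed was at most 0.00289 of it. This argues only against carry-over of 1 NSG library as the source of the whole share in another NSG mouse. Other kinds of contamination, such as of this barcode alone, were not tested. Whether the cells given to NSG and Ptprca mice differed before injection cannot be told apart from a host effect, since 1 baseline sample was analysed. A host effect on this founder stays open as a hypothesis.

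The lower effective number of barcodes in spleen was set against fewer reads and fewer template molecules. In Ptprca mice 2 and 3 the spleen had at least 1.24 times the reads of the bone marrow, which argues against reads there. In the other 4 mice it had fewer. Thinning the bone marrow of Ptprca mouse 1 to the spleen's reads left 64.4 effective barcodes, against 17.2 in its spleen. In NSG mice 4, 5 and 6 thinning left 43.8, 41.4 and 41.5, against 5.24, 25.7 and 9.78 in spleen. The ratio of bone marrow to spleen stayed at 1.61 or more. These simulated values argue against fewer reads as the cause in those mice. In Ptprca mice the templates per repeat, estimated from the disagreement of repeats, were at least 1.74 times higher in spleen than in bone marrow, which argues against templates there. NSG spleens had an estimated 7821, 6185 and 7868 templates against 37868, 49224 and 63630 in bone marrow, and drawing that many from the bone marrow shares left a ratio of at least 1.59, a simulated value that excludes nothing, so fewer templates stay open. The organ itself was not tested as a cause, and the same barcodes rising in spleens of separate mice of a strain stays open. Mean rho between mice of a strain was 0.0632 over 132 barcodes, with permutation p = 0.0425 and a highest shuffled value of 0.165. The shuffles treat barcodes as independent, which they are not. Within strains rho ran from -0.190, between Ptprca mice 1 and 3, to 0.279, between Ptprca mice 1 and 2.

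Rare barcodes linked the bone marrow libraries of Ptprca mouse 1 and NSG mouse 5, found by screening 120 ordered pairs of libraries. Of the 21 barcodes at 1000 CPM or more in mouse 5 and at 0 in the spleen of mouse 1, 100% were seen in mouse 1 bone marrow, at a median of 0.0663% of the donor, against at most 60% for other donors with at least 5 such barcodes into that library (1 donor with fewer had 2 of 3). In the reverse direction 22 of 22 were seen, at a median of 0.362% and an SD of the log2 ratio of 3.28, but mouse 5 bone marrow held at least 66.7% of such barcodes of every donor, and 100% of the 6 of 1 other. The first direction is consistent with exchange of reads or DNA between the libraries. Growth of the same rare clones in both mice stays open. The SD of the log2 ratio was 0.680, and rho between donor and recipient values was 0.925. This SD was below the lowest of 27 other pairs, 0.913, and their median, 4.06. That lowest pair, with NSG mouse 6 spleen as donor and 5 barcodes seen, had the same recipient. The SD was not under the limit for excluding growth, 0.5 of the lowest value, set after the result was seen.

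For the counts of called barcodes, 10 splits of 6 mice cannot give a share under 0.05. In bone marrow the real split gave 4 calls and the highest other 0, with 1 split as large, and in spleen likewise 4, 0 and 1. For the organ contrast within NSG mice, 10 splits of their 6 libraries gave 1 for the real labels and 1 as the highest other, with 2 splits as large. Where the real count was 0, every split reaches it, so the splits say nothing about chance. This holds for the interaction (10 of 10 splits, the highest other 0), the organ contrast within Ptprca mice (10 of 10, the highest other 1) and the organ contrast over both strains (100 of 100 label draws within strains, the highest other 1).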
